A study of Mus musculus with 16 samples.

How the data were processed

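Gene expression was taken from the 16 deposited tables, which per the labels hold FPKM, 1 table per library. Per the submitters' processing notes, base calls were made with bcl2fastq 2.17, reads were aligned with STAR to mm10, and counting was done with HTSeq. Each table listed 24060 gene labels, of which 27 had been turned into dates by a spreadsheet program and are not named here, and 2 were repeated. Of the labels, 23593 (98.1%) were found in GENCODE vM21 (GRCm38/mm10), from which the coordinates were taken. Sums of FPKM over genes ran from 216830.8 to 246166.1.

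Count tests had been planned before the data were examined, and they were not run because the deposited unit is FPKM. In their place, log2(FPKM/f + 1) was fitted with limma 3.58.1 in R 4.3.3, where f is a trimmed-mean scaling factor (0.777 to 1.28) computed on FPKM with 30% of log ratios and 5% of levels trimmed. The scale, the factors and the filter were chosen after the unit was seen. Genes were kept with at least 1 FPKM in at least 4 libraries, which left 13470. All 16 libraries entered a single fit with the 4 groups as terms (12 residual degrees of freedom), and moderated t-tests with trended, robust variance were adjusted by the Benjamini-Hochberg method, with calls at adjusted p under 0.05. The 5 comparisons were IP against input in each region, striatum against hippocampus in IP and in input, and the difference of these last 2. The IP-enriched regional genes were those called between the IPs and above log2 1 in IP over input in the region where they were higher. This set uses the same IP libraries in both criteria, so chance was weighed for it only by splits of the libraries into other groups.

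Genes were named by a rule fixed in advance: Aldh1l1, Crym, Gfap and Rpl22, then the largest fold changes per direction among called genes with the same sign in all 4 animals and a group mean of at least 5 scaled FPKM, which took the place of a minimum on counts. Up to 4 members of each list with the smallest p were also available for naming. Some genes that met this rule are not reported here. The 37 gene lists, 13 of cell types and 24 of functions, were fixed from general knowledge before the data were examined. The red blood cell list had 1 measured member and was not tested, which left 36. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists within each comparison, and again with a correlation estimated for each list.

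The libraries of each animal were paired by the labels. After group means were removed, the correlation across genes of the same animal's hippocampal and striatal IP was 0.303 to 0.525 and was the best match in all 4 animals. Same-animal values were 0.086 to 0.171 for hippocampal input with hippocampal IP, 0.054 to 0.318 for the 2 inputs, and -0.008 to 0.085 for striatal input with striatal IP, where the own partner was best in 2 animals. The animal was not a term of the main fit and entered as a block in an alternative.

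Depth was estimated from the step between FPKM values of a gene and its GENCODE length, with 1351 of 1353 genes (99.9%) on whole-read steps, and its absolute size rests on those lengths. Estimated depth differed 5.46-fold between libraries. The kit does not mark strand, so antisense and overlapping genes share reads. The mice were of an FVB background crossed back to C57BL/6N, and the sex of each animal was not in the labels. Carry-over was the median ratio of IP to input over the pan-neuronal markers, per library and in percent of the same animal's input. In the subtraction, input times that share was taken from the IP value, and the scaling factors were computed anew before log2 was taken. No value was allowed to turn negative.

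The procedure was tested on simulated data with 13055 genes. Between IPs, 10.4% of genes changed 1.5-fold, 68.7% of genes changed 2-fold and 98.4% of genes changed 4-fold were called, and for the difference of differences 0%, 17.9% and 98.4%. Unchanged genes made up 5.7% and 10.8% of the calls. A list changed 1.5-fold had adjusted p = 2.94e-15, and adjusted p = 2.25e-05 with an estimated correlation, and 0 of 20 unchanged lists were called. Genes were drawn independently at a dispersion of 0.05, with no animal effect and no carry-over. Correlation within lists, estimated at 0.521 for the real astrocyte list, was thus absent. The simulation cannot tell whether the preset correlation gives false list calls in the real data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.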

Results

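RNA was sequenced from the hippocampus and the striatum of 4 RiboTag mice at postnatal day 63. In RiboTag mice, Cre recombinase switches on a hemagglutinin (HA) tag on the ribosomal protein Rpl22, and here an Aldh1l1 driver placed the tag in astrocytes, the star-shaped glia that take up transmitter and potassium. From each region, RNA was taken from the cleared tissue lysate (input) and from ribosomes precipitated with an antibody to the tag (IP). The animals, numbered 970, 971, 974 and 977, each gave all 4 kinds of library, so each group held 4 libraries and the series 16. Estimated depth was 9.03 to 12.24 counted fragments (in units of 1e6) in hippocampal input, 18.9 to 22.61 in hippocampal IP, 4.14 to 8.96 in striatal input and 13.95 to 21.76 in striatal IP. Group values below are scaled FPKM as mean ± SD over 4 animals, and fold changes are on the log2(FPKM + 1) scale ± SE, which understates changes of low genes.

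The first question was which RNAs the precipitation enriched. In the hippocampus, astrocyte genes rose in IP over input. Aldh1l1, the gene of a folate enzyme and the driver of the Cre line, went from 4.58 ± 1.34 to 106 ± 9.86 (log2 fold change 4.29 ± 0.19, adjusted p = 2.21e-11). Gfap, the astrocyte intermediate filament gene, went from 15.4 ± 1.18 to 268 ± 22.4 (log2 fold change 4.03 ± 0.22, adjusted p = 1.98e-10). Neuronal genes fell. The synaptic fusion protein gene Snap25 went from 1927 ± 77.4 to 68.4 ± 19.7 (log2 fold change -4.83 ± 0.25, adjusted p = 8.46e-11). The neuropeptide gene Sst went from 372 ± 48.1 to 8.93 ± 2.84 (log2 fold change -5.27 ± 0.31, adjusted p = 3.34e-10). In the striatum, Aldh1l1 rose from 4.41 ± 1.05 to 104 ± 25.3 (log2 fold change 4.26 ± 0.19, adjusted p = 4.53e-11) and Gfap from 2.44 ± 1.31 to 48.5 ± 12.6 (log2 fold change 3.90 ± 0.22, adjusted p = 4.19e-10). Crym, which encodes the thyroid hormone-binding mu-crystallin, fell in hippocampal IP by 3.11 on the log2 scale (adjusted p = 5.87e-09) and rose in striatal IP by 2.66 (adjusted p = 4.51e-08). Rpl22 itself, the tagged protein's gene, did not pass in either region (-0.20, adjusted p = 0.104 in hippocampus and -0.02, adjusted p = 0.878 in striatum). Crym and Gfap are known to have been followed up in the study, so their values here are not independent evidence.

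Large rises in hippocampal IP under the fixed rule were Acsbg1, an acyl-CoA synthetase (4.58), the glycolytic enzyme gene Aldoc (4.47), angiotensinogen (Agt, 4.44), and the apolipoprotein genes Apoe (4.42) and Clu (4.40), with adjusted p from 6.30e-12 to 7.07e-08. The largest falls were Sst (-5.27), Vsnl1 (-4.94), Snap25 (-4.83), Pcp4 (-4.54), Basp1 (-4.54) and the neuropeptide gene Cck (-4.48). In striatal IP the largest rises were Apoe (4.99), Aldoc (4.80), the scaffold gene Slc9a3r1 (4.77), the GABA transporter gene Slc6a11 (4.71), the receptor gene Gpr37l1 (4.57) and the serine synthesis enzyme gene Phgdh (4.53). Each of these was lower in striatal inputs 971 and 974 than in 970 and 977. Apoe stood at 76.7 and 39.1 against 169 and 201, and Phgdh at 3.86 and 1.90 against 10.8 and 11.6. The size and order of these rises thus rest partly on inputs 971 and 974. Large striatal falls were Sst (-5.64), Pcp4 (-5.33), Vsnl1 (-5.03), the lipocalin gene Apod (-4.85) and Snap25 (-4.77). The rule kept only genes that moved the same way in all 4 animals.

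Among the cell type lists, astrocyte genes rose in both regions (medians 3.87 and 3.63, adjusted p = 2.99e-17 and 6.11e-16). Of 25 members, 25 were higher and 0 lower in hippocampus, and 25 and 0 in striatum, or 25 and 0, and 25 and 0, adjusted over the list alone. The list had adjusted p = 0.0545 and 0.0641 with an estimated correlation. Its members with the smallest p were the zinc transporter gene Slc39a12 (4.08 and 4.06), the transcription factor gene Sox9 (3.87 and 3.82) and the glutamate transporter gene Slc1a3 (4.37 and 4.11). Here and below, paired values give hippocampus first and striatum second, and single values after gene names are log2 fold changes. Pan-neuronal genes fell in both regions (medians -3.67 and -3.09, adjusted p = 1.32e-08 and 3.95e-08). Of 16 members, 0 were higher and 16 lower in hippocampus, and 0 and 15 in striatum, or 0 and 16, and 0 and 15, adjusted over the list alone. Among them was the tubulin-binding gene Stmn2 (-4.14 and -2.50), and the list had adjusted p = 0.0545 and 0.0641 with an estimated correlation. The IP level of the pan-neuronal markers, as a percent of input, had a median of 6.43 ± 2.20 in hippocampus and 11.4 ± 4.25 in striatum (n = 4 each). In animal 974 it was 9.47 and 16.4.

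**Figure D1:**
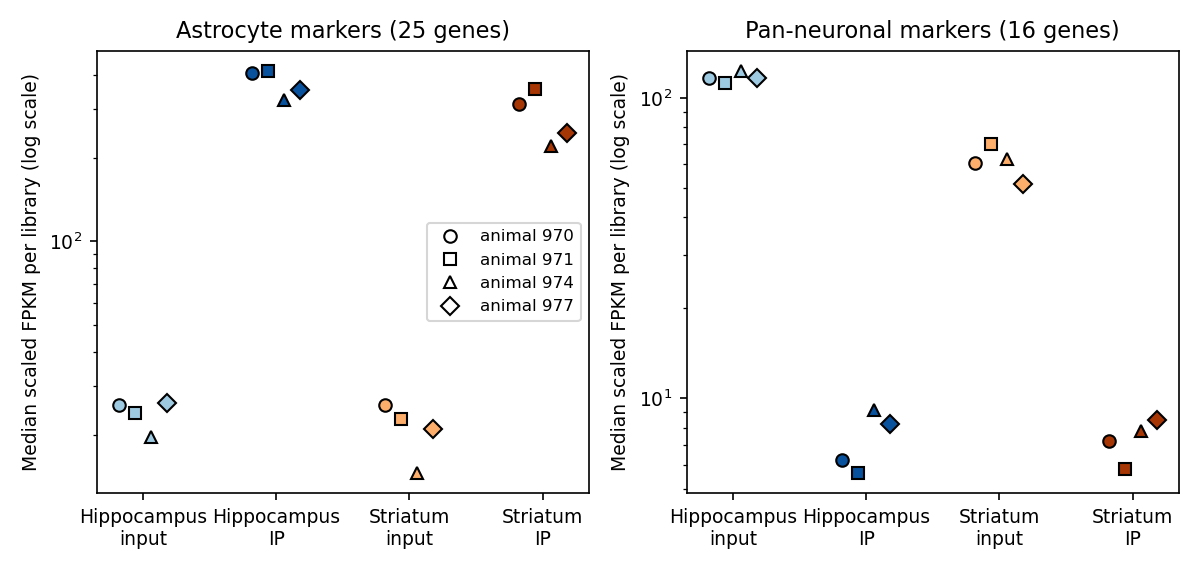
Median scaled FPKM per library (log scale) of the 25 astrocyte and the 16 pan-neuronal markers in the 4 groups, with a symbol for each animal. Astrocyte medians were 14.6 to 26.2 in inputs and 221 to 414 in IPs.

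Other cell types were depleted by the precipitation. Oligodendrocyte genes fell (medians -2.52 and -2.46, adjusted p = 0.000456 and 5.76e-06). The myelin gene Mal was at -3.61 and -4.29, and the list had adjusted p = 0.242 and 0.116 with an estimated correlation. Of 18 members, 2 were higher and 16 lower in hippocampus, and 0 and 16 in striatum, or 2 and 16, and 0 and 16, adjusted over the list alone. Microglial genes fell (medians -1.94 and -1.81, adjusted p = 2.41e-05 and 2.06e-06), among them the protease gene Ctss (-3.07 and -3.41). These calls held at adjusted p = 0.0444 and 0.0312 with an estimated correlation. Of 15 members, 0 were higher and 14 lower in hippocampus, and 0 and 14 in striatum, or 0 and 15, and 0 and 14, adjusted over the list alone. Interneuron genes fell (medians -2.68 and -2.06, adjusted p = 2.41e-05 and 7.83e-05). The neuropeptide gene Npy was at -4.06 and -4.45, and the list had adjusted p = 0.0545 and 0.0641 with an estimated correlation. Of 11 members, 0 were higher and 10 lower in hippocampus, and 0 and 8 in striatum, or 0 and 10, and 0 and 8, adjusted over the list alone. Hippocampal principal neuron genes fell in hippocampal IP (median -2.69, adjusted p = 1.02e-06), a call that held at adjusted p = 0.0456 with an estimated correlation. C1ql2, which encodes a synaptic adhesion ligand, was at -2.70. Of 18 members, 1 was higher, 17 lower and 0 not passing, or 1 higher and 17 lower adjusted over the list alone. Striatal projection neuron genes fell in striatal IP (median -2.43, adjusted p = 6.74e-09), with adjusted p = 0.0641 with an estimated correlation. Drd1a, the dopamine D1 receptor gene, was at -2.91. Of 19 members, 0 were higher, 19 lower and 0 not passing, or 0 higher and 19 lower adjusted over the list alone. In the other region each list fell less. The striatal list had a median -0.90, adjusted p = 0.0458 in hippocampus, adjusted p = 0.474 with an estimated correlation, and adjusted p = 0.0663 with the animals as blocks. Of 19 members, 1 was higher, 11 lower and 7 not passing, or 1 higher and 11 lower adjusted over the list alone. The hippocampal list had a median -0.56, adjusted p = 0.0456 in striatum, and adjusted p = 0.296 with an estimated correlation. Of 18 members, 1 was higher, 12 lower and 5 not passing, or 2 higher and 12 lower adjusted over the list alone. With no scaling both the striatal projection neuron and the hippocampal principal neuron calls in the other region were lost (adjusted p = 0.29 and 0.151). Endothelial genes fell (medians -1.08 and -0.94, adjusted p = 0.0102 and 0.00252). Itm2a, a membrane protein gene, was at -2.06 and -2.83, and the list had adjusted p = 0.0992 and 0.0641 with an estimated correlation. Of 7 members, 0 were higher and 7 lower in hippocampus, and 0 and 7 in striatum, or 0 and 7, and 0 and 7, adjusted over the list alone. Oligodendrocyte precursor genes fell too (medians -1.16 and -1.44, adjusted p = 0.0132 and 0.00223). The growth factor receptor gene Pdgfra was at -1.59 and -1.44, and the list had adjusted p = 0.0628 and 0.0568 with an estimated correlation. Of 7 members, 0 were higher and 5 lower in hippocampus, and 0 and 6 in striatum, or 0 and 5, and 0 and 7, adjusted over the list alone. The mural (medians -0.93 and -0.60, adjusted p = 0.781 and 0.552) and the ependymal and choroid plexus lists (medians -0.46 and -0.02, adjusted p = 0.522 and 0.844) did not pass. The progenitor list did not pass either (medians -0.37 and 0.35, adjusted p = 0.626 and 0.0748), and the pericyte marker Pdgfrb rose (2.40 and 2.58).

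Genes of astrocyte functions were enriched. Cholesterol synthesis genes rose (medians 1.97 and 1.85, adjusted p = 8.57e-11 and 8.62e-09), with the sterol enzyme genes Lss at 2.33 and Cyp51 at 2.41 in hippocampus and Sc5d at 2.08 in striatum. The list had adjusted p = 0.0351 and 0.0534 with an estimated correlation. Of 22 members, 22 were higher and 0 lower in hippocampus, and 21 and 1 in striatum, or 22 and 0, and 21 and 1, adjusted over the list alone. Lipid transport and fatty acid genes rose (medians 2.998 and 2.82, adjusted p = 3.32e-10 and 3.14e-09). The desaturase gene Fads2 was at 4.06 and 4.47, and the list had adjusted p = 0.0456 and 0.0568 with an estimated correlation. Of 21 members, 19 were higher and 2 lower in hippocampus, and 19 and 2 in striatum, or 19 and 2, and 19 and 2, adjusted over the list alone. Potassium, water and ion transport genes rose (medians 3.20 and 2.24, adjusted p = 9.87e-08 and 1.53e-05). The potassium channel gene Kcnj10 was at 3.81 and 3.23, and the list had adjusted p = 0.0456 and 0.0641 with an estimated correlation. Of 17 members, 15 were higher and 1 lower in hippocampus, and 14 and 2 in striatum, or 15 and 2, and 14 and 2, adjusted over the list alone. Glutamate and GABA uptake genes rose (medians 2.95 and 2.70, adjusted p = 3.27e-05 and 0.000119). The glutamine transporter gene Slc38a3 was at 3.92 and 4.18, and the list had adjusted p = 0.0786 and 0.0952 with an estimated correlation. Of 17 members, 13 were higher and 4 lower in hippocampus, and 13 and 4 in striatum, or 13 and 4, and 13 and 4, adjusted over the list alone. Glycolysis and glycogen genes rose (medians 1.21 and 1.41, adjusted p = 6.97e-07 and 2.55e-08). The glycogen phosphorylase gene Pygm was at 4.23 and 3.69, and the list had adjusted p = 0.197 and 0.126 with an estimated correlation. Of 24 members, 18 were higher and 0 lower in hippocampus, and 24 and 0 in striatum, or 18 and 0, and 24 and 0, adjusted over the list alone. Connexin genes rose (medians 2.60 and 2.36, adjusted p = 0.00264 and 0.00393). Connexin 43 (Gja1) was at 4.20 and 3.74, and the list had adjusted p = 0.0628 and 0.0688 with an estimated correlation. Of 6 members, 5 were higher and 1 lower in hippocampus, and 5 and 1 in striatum, or 5 and 1, and 5 and 1, adjusted over the list alone.

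Signalling and matrix genes followed the same direction. Notch genes rose (medians 1.58 and 1.47, adjusted p = 1.61e-05 and 2.72e-05), with the receptor gene Notch1 at 3.34 and 3.66. These calls held at adjusted p = 0.0351 and 0.0312 with an estimated correlation. Of 16 members, 14 were higher and 2 lower in hippocampus, and 14 and 1 in striatum, or 14 and 2, and 14 and 1, adjusted over the list alone. Hedgehog genes rose (medians 1.91 and 1.98, adjusted p = 0.000184 and 0.00110). The effector gene Gli2 was at 3.001 and 3.10, and the list had adjusted p = 0.0504 and 0.0641 with an estimated correlation. Of 10 members, 8 were higher and 1 lower in hippocampus, and 8 and 1 in striatum, or 8 and 1, and 9 and 1, adjusted over the list alone. The Wnt list tested higher (medians 0.90 and 1.25, adjusted p = 0.000490 and 3.08e-05). The receptor gene Fzd2 was at 3.11 and 3.53, and the list had adjusted p = 0.197 and 0.116 with an estimated correlation. Of 21 members, 11 were higher and 3 lower in hippocampus, and 17 and 2 in striatum, or 11 and 3, and 17 and 2, adjusted over the list alone. Extracellular matrix genes rose (medians 2.64 and 2.39, adjusted p = 3.03e-05 and 2.72e-05) and held at adjusted p = 0.0351 and 0.0312 with an estimated correlation. Of 18 members, 12 were higher and 2 lower in hippocampus, and 14 and 2 in striatum, or 12 and 2, and 14 and 2, adjusted over the list alone. Timp3, a protease inhibitor gene, was at 3.19 and 3.31, while the perineuronal net gene Hapln4 fell in hippocampus (-3.36). Synapse formation and engulfment genes rose (medians 1.34 and 2.41, adjusted p = 0.00291 and 4.96e-05). The engulfment receptor gene Mertk was at 3.29 and 3.22, and the list had adjusted p = 0.164 and 0.0688 with an estimated correlation. Of 16 members, 9 were higher and 3 lower in hippocampus, and 11 and 1 in striatum, or 9 and 3, and 11 and 1, adjusted over the list alone. The G protein-coupled receptor list tested higher (medians 0.91 and 1.10, adjusted p = 0.00368 and 0.00266). The endothelin receptor gene Ednrb was at 3.26 and 2.92, and the list had adjusted p = 0.142 and 0.116 with an estimated correlation. Of 25 members, 15 were higher and 6 lower in hippocampus, and 17 and 6 in striatum, or 16 and 6, and 17 and 6, adjusted over the list alone. Intermediate filament and linker genes rose (medians 2.39 and 1.63, adjusted p = 0.00114 and 0.000852), with vimentin (Vim) at 3.39 and 2.67. They held at adjusted p = 0.0351 and 0.0312 with an estimated correlation. Of 7 members, 6 were higher and 1 lower in hippocampus, and 6 and 0 in striatum, or 6 and 1, and 6 and 0, adjusted over the list alone. The list of interferon response and antigen presentation tested higher (medians 0.62 and 0.59, adjusted p = 0.0216 and 0.0403). The antigen-presenting gene H2-K1 was at 2.78 and 2.71, and the list had adjusted p = 0.0628 and 0.0878 with an estimated correlation. Of 12 members, 7 were higher and 0 lower in hippocampus, and 6 and 1 in striatum, or 7 and 0, and 6 and 1, adjusted over the list alone. Its striatal call was lost without animal 971 (adjusted p = 0.0638) or 977 (adjusted p = 0.0636). The pan-reactive astrocyte genes, among which Gfap and Vim also stand in other lists, rose (medians 1.20 and 1.17, adjusted p = 0.0132 and 0.0481). They had adjusted p = 0.0545 and 0.0952 with an estimated correlation, and both calls were lost without animal 974 (adjusted p = 0.0521 and 0.0658). Of 8 members, 6 were higher and 2 lower in hippocampus, and 5 and 2 in striatum, or 6 and 2, and 5 and 2, adjusted over the list alone.

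Some groups fell or did not pass. Genes of cytosolic ribosomal proteins fell (medians -0.66 and -0.44, adjusted p = 2.41e-05 and 0.000600), with Rps15a at -1.65 in hippocampus and Rps20 at -1.35 in striatum. The list had adjusted p = 0.248 and 0.314 with an estimated correlation. Of 74 members, 1 was higher and 52 lower in hippocampus, and 7 and 38 in striatum, or 1 and 52, and 6 and 37, adjusted over the list alone. These short genes have many processed pseudogenes that can share their reads, so single members are uncertain. Genes of calcium signalling and handling fell in hippocampus (median -1.06, adjusted p = 0.0222), with adjusted p = 0.103 with an estimated correlation, and the call was lost with no scaling (adjusted p = 0.0616). Of 25 members, 5 were higher, 15 lower and 5 not passing, or 5 higher and 15 lower adjusted over the list alone. The exchanger gene Slc8a1 was at -2.85 there, and the inositol trisphosphate receptor gene Itpr2 rose (2.73). In striatum the list did not pass (median -0.95, adjusted p = 0.0530) but did with animal blocks (0.0489) or a rotation test. Immediate early genes did not pass (medians -1.27 and -0.79, adjusted p = 0.0935 and 0.105). They did with animal blocks (0.0371, 0.0489) or a rotation test. Egr1, a gene switched on by activity, fell in both (-3.55 and -3.49). The list of oxidative phosphorylation, nuclear-encoded, did not pass in hippocampus (median 0.11, adjusted p = 0.200) and tested higher in striatum (median 0.43, adjusted p = 0.0247). The striatal call had adjusted p = 0.563 with an estimated correlation and was lost without animal 971 (adjusted p = 0.191). Of 89 members, 41 were higher, 13 lower and 35 not passing, or 41 higher and 13 lower adjusted over the list alone. Pallial transcription factor genes did not pass in hippocampus (median 0.79, adjusted p = 0.197) and rose in striatum (median 0.9994, adjusted p = 0.00910). Lhx2 was at 2.63 and 3.37, and the striatal call had adjusted p = 0.116 with an estimated correlation. Of 12 members, 7 were higher, 1 lower and 4 not passing, or 7 higher and 1 lower adjusted over the list alone. Subpallial transcription factor genes did not pass in hippocampus (median -0.16, adjusted p = 0.342) and fell in striatum (median -1.24, adjusted p = 0.000813). The interneuron gene Lhx6 was at -1.74 in striatum, and that call had adjusted p = 0.0568 with an estimated correlation. Of 16 members, 1 was higher, 13 lower and 2 not passing, or 1 higher and 13 lower adjusted over the list alone. The A1-type (medians 0.26 and 0.23, adjusted p = 0.961 and 0.918), A2-type (medians -1.11 and -0.63, adjusted p = 0.318 and 0.195) and thyroid hormone lists (medians 0.62 and 1.30, adjusted p = 0.191 and 0.0748) did not pass. The A1-type list had mean log2 fold changes of -0.08 and -0.03, opposite in sign to its medians and test.

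Across 13470 genes tested with limma, 3853 were higher and 4993 lower in hippocampal IP, and 4327 were higher and 4456 lower in striatal IP. At least 2-fold, 1972 were higher and 2464 lower in hippocampus, and 2129 and 2063 in striatum. Of the calls, 43.6% in hippocampus and 49.3% in striatum were rises, which became 26% and 36.1% with no scaling of the deposited values. The calls overlapped between regions, with 3234 genes higher in both (1238 for independent lists) and 3582 lower in both (1652). Across genes, which are not independent replicates, the enrichment in hippocampus and striatum had Pearson's r = 0.873 and Spearman's rho = 0.838.

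The main question was how astrocyte RNA differed between the regions. Crym (chromosome 7, 120186380 to 120202111, GRCm38/mm10) was higher in striatal than in hippocampal IP, at 284 ± 73.1 against 8.36 ± 3.6 (log2 fold change 4.98 ± 0.23, adjusted p = 9.82e-10), a difference of 31.5-fold. Gfap (chromosome 11, 102887336 to 102900912) was lower in striatal IP, at 48.5 ± 12.6 against 268 ± 22.4 (log2 fold change -2.47 ± 0.22, adjusted p = 1.58e-06). Aldh1l1 did not pass, at 104 ± 25.3 against 106 ± 9.86 (log2 fold change -0.07 ± 0.19, adjusted p = 0.881), and neither did Rpl22 (log2 fold change -0.08 ± 0.11, adjusted p = 0.729). In total, 975 genes were higher and 665 lower in striatal IP, of which 410 and 176 differed by at least 2-fold. Of the 975 and 665 genes, 107 higher and 300 lower ones were also enriched over input by more than log2 1 in the region where they were higher, while 412 higher and 174 lower ones were depleted there (log2 under -1).

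Among the IP-enriched genes higher in striatum, Scel (chromosome 14, 103513342 to 103612797), which encodes the cornified envelope precursor sciellin, stood at 19.4 ± 5.97 against 0.149 ± 0.0953 (log2 fold change 4.12 ± 0.24, adjusted p = 1.42e-08). Top2a (chromosome 11, 98992943 to 99024189), the DNA topoisomerase of dividing cells, stood at 10.9 ± 5.01 against 0.856 ± 0.402 (log2 fold change 2.62 ± 0.23, adjusted p = 9.13e-07). Ube2c, a mitotic ubiquitin-conjugating enzyme gene, stood at 6.18 ± 1.8 against 0.387 ± 0.176 (2.35). The retinoid isomerase gene Rpe65 (2.58) and the secreted Wnt antagonist gene Sfrp5 (2.35) were also higher. The serine protease gene Prss56 was listed at 0 in all 4 hippocampal IPs and at 12.7, 3.93, 11.3 and 6.999 in the striatal IPs (adjusted p = 1.70e-07). The histone gene Hist1h2bm rose by 2.11, but near-identical histone genes can share its reads, and 2610034M16Rik, an unnamed gene model, rose by 2.12. The microRNA locus Mir667 had 2.25 (adjusted p = 0.00296), lost without animal 974 (adjusted p = 0.0665), and at such short loci reads of longer overlapping transcripts cannot be told apart.

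Among the IP-enriched genes higher in hippocampus, Myoc (chromosome 1, 162639155 to 162649693), which encodes the secreted glycoprotein myocilin, stood at 97.6 ± 30.7 against 2.91 ± 1.71 in striatal IP (log2 fold change -4.70 ± 0.28, adjusted p = 1.43e-08). Serpinf1 (chromosome 11, 75409769 to 75422701), the gene of pigment epithelium-derived factor, stood at 43.9 ± 8.89 against 1.84 ± 0.830 (log2 fold change -4.01 ± 0.24, adjusted p = 1.42e-08), and the desmosome gene Dsp (chromosome 13, 38151294 to 38198577) at 13.6 ± 5.53 against 0.135 ± 0.138 (-3.63). The homeodomain-only gene Hopx (chromosome 5, 77086988 to 77115121) stood at 55.2 ± 4.94 against 4.19 ± 0.541 (log2 fold change -3.44 ± 0.11, adjusted p = 1.92e-11), and the zinc finger transcription factor gene Zic2 (chromosome 14, 122475435 to 122479852) at 9.41 ± 0.227 against 0.323 ± 0.123 (log2 fold change -2.98 ± 0.11, adjusted p = 2.64e-11). Also lower in striatal IP were the actin-binding protein gene Cald1 (-2.87), the receptor transporter gene Rtp1 (-2.82), the matrix proteoglycan gene Prelp (-2.38) and the ferric reductase gene Cybrd1 (-2.30). As in the previous comparisons, the same sign in all 4 animals was part of the rule.

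**Figure D2:**
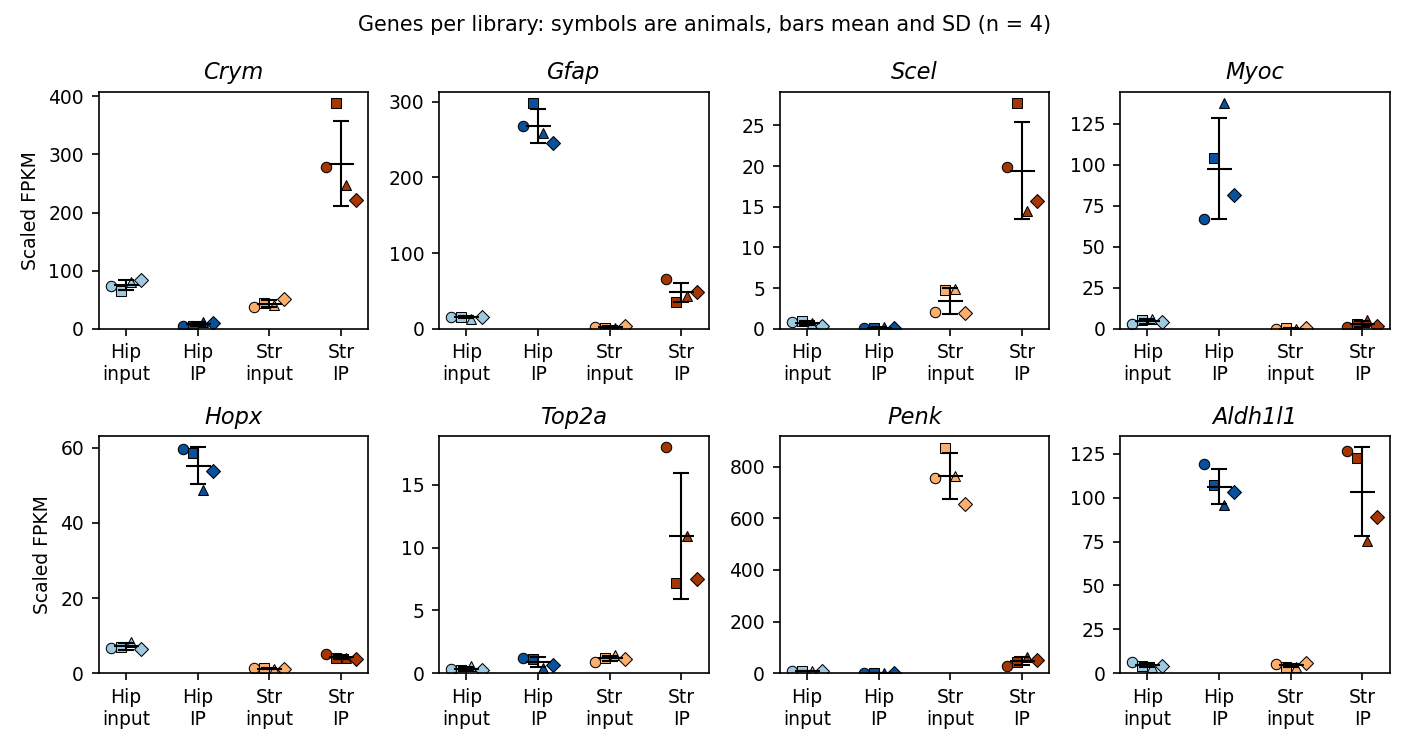
Scaled FPKM of 8 genes in each library, with a symbol per animal and bars at the mean and SD of 4 animals. Crym stood at 284 ± 73.1 in striatal IP and 8.36 ± 3.60 in hippocampal IP.

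Genes of the local neurons differed between the IPs in the direction of the tissue. Striatal projection neuron genes rose in striatal IP (median 2.37, adjusted p = 9.65e-25), a call that held at adjusted p = 0.00778 with an estimated correlation. Of 19 members, 17 were higher, 1 lower and 1 not passing, or 17 higher and 1 lower adjusted over the list alone. Among them was enkephalin (Penk), at 46.7 ± 14.3 against 0.570 ± 0.451 (4.92), with the phosphodiesterase gene Pde10a at 3.36 and the dopamine receptor gene Drd2 at 4.79. Penk was at 763 ± 88.9 in striatal input. Its regional difference turned to -0.15 (adjusted p = 0.505) after a share of input, set by the pan-neuronal markers, was subtracted from each IP. In each animal that share exceeded Penk's own striatal IP level, which the subtraction therefore set to 0. Drd2 lost its call too (adjusted p = 0.448), with the share near or above its IP level in animals 970, 971 and 974. Given the size of the share, neither loss is a separate test. Hippocampal principal neuron genes fell (median -0.75, adjusted p = 9.53e-13) and held at adjusted p = 0.00778 with an estimated correlation. Of 18 members, 0 were higher, 11 lower and 7 not passing, or 1 higher and 12 lower adjusted over the list alone. They included the neuritin gene Nrn1 (-3.76), Dsp (-3.63) and the transcription factor gene Neurod2 (-2.18). The interneuron list tested higher (median 0.10, adjusted p = 0.0378), with the GABA synthesis gene Gad2 at 2.01. That list had adjusted p = 0.318 with an estimated correlation. After the subtraction the interneuron list (adjusted p = 0.528) and Gad2 (adjusted p = 1) lost their calls, as the list did with no scaling (adjusted p = 0.177). Of 11 members, 4 were higher, 0 lower and 7 not passing, or 5 higher and 0 lower adjusted over the list alone. The oligodendrocyte list tested higher (median 0.84, adjusted p = 3.33e-05), with adjusted p = 0.266 with an estimated correlation. Of 18 members, 9 were higher, 1 lower and 8 not passing, or 14 higher and 1 lower adjusted over the list alone. The subtraction ended the oligodendrocyte call (adjusted p = 0.547). The pan-neuronal list did not pass (median -0.13, adjusted p = 0.478). Carry-over of pan-neuronal RNA, as a share of input, was larger in striatal IP, at 11.4% ± 4.25 against 6.43% ± 2.20 in hippocampal IP. The pan-neuronal median itself was alike in the IPs, at 5.65 to 9.15 scaled FPKM in hippocampus and 5.83 to 8.48 in striatum. The inputs differed, at 112 to 123 in hippocampus and 51.6 to 70.3 in striatum.

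The astrocyte list tested lower in striatal IP (median -0.34, adjusted p = 2.74e-06), with adjusted p = 0.318 with an estimated correlation. Of 25 members, 0 were higher, 6 lower and 19 not passing, or 0 higher and 9 lower adjusted over the list alone. The level of these markers went with carry-over. Their median was 314 and 355 scaled FPKM in striatal IPs 970 and 971, with carry-over of 7.83% and 7.95%, and 221 and 248 in 974 and 977, with 16.45% and 13.42%. In hippocampal IPs it was 407 and 414 in 970 and 971 (5.18% and 4.51%), and 325 and 353 in 974 and 977 (9.47% and 6.56%). Xist and Y-linked genes parted the same animals, so carry-over and sex cannot be told apart here. Besides Gfap, the connexin 30 gene Gjb6 was lower (-0.80, adjusted p = 0.00285). Aquaporin 4 (Aqp4) was at -1.06, adjusted p = 0.00737, a call lost without animal 971 (adjusted p = 0.0741). Cholesterol synthesis genes fell (median -0.50, adjusted p = 6.31e-12) and held at adjusted p = 0.0159 with an estimated correlation. Of 22 members, 0 were higher, 14 lower and 8 not passing, or 0 higher and 17 lower adjusted over the list alone. The smallest p were those of Cyp51 (-0.75, adjusted p = 0.000170) and squalene epoxidase (Sqle, -0.68, adjusted p = 0.00174), and the Cyp51 call was lost with animals 974 and 977 left out (adjusted p = 0.0511). Pan-reactive astrocyte genes fell (median -0.73, adjusted p = 6.54e-06) and held at adjusted p = 0.00558 with an estimated correlation. Of 8 members, 0 were higher, 4 lower and 4 not passing, or 0 higher and 4 lower adjusted over the list alone. The oncostatin M receptor gene Osmr was at -1.32, Vim at -0.87 and the asparaginase gene Aspg at -0.96. The intermediate filament list, which shares Gfap and Vim with the previous one, tested lower (median -0.24, adjusted p = 0.00637) and held at adjusted p = 0.0367 with an estimated correlation. Of 7 members, 1 was higher, 3 lower and 3 not passing, or 1 higher and 3 lower adjusted over the list alone. The list of potassium, water and ion transport tested lower (median -0.34, adjusted p = 0.00353), with adjusted p = 0.266 with an estimated correlation. Of 17 members, 1 was higher, 3 lower and 13 not passing, or 1 higher and 3 lower adjusted over the list alone. The potassium channel genes Kcnj16 (-1.88) and Kcnk2 (-0.84) were lower. The list of glutamate and GABA uptake and metabolism tested lower (median -0.35, adjusted p = 0.00702), with adjusted p = 0.317 with an estimated correlation. Of 17 members, 0 were higher, 4 lower and 13 not passing, or 1 higher and 6 lower adjusted over the list alone. The mitochondrial glutamate carrier gene Slc25a18 was at -1.97, and the list call was lost with animals 974 and 977 left out (adjusted p = 0.0579).

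Regional transcription factor genes differed between the IPs in the direction of the inputs. Subpallial factors rose in striatal IP (median 1.23, adjusted p = 2.05e-12) and held at adjusted p = 0.00196 with an estimated correlation. Of 16 members, 11 were higher, 1 lower and 4 not passing, or 12 higher and 1 lower adjusted over the list alone. The subpallial transcription factors as a list were lower in striatal IP than in its input (median -1.24) and differed more between the inputs (median 1.56), as did neuronal genes, and carry-over was 11.4% in striatal against 6.43% in hippocampal IP. After the carry-over subtraction their median was 0.67 (adjusted p = 4.67e-08). Six3 stood at 18.6 ± 3.96 against 0.0967 ± 0.0664 (4.14), with Dlx2 at 2.16, Sp9 at 1.88 and Meis1 at 1.24. Pallial factors fell (median -0.66, adjusted p = 1.29e-07) and held at adjusted p = 0.0125 with an estimated correlation. Of 12 members, 1 was higher, 9 lower and 2 not passing, or 1 higher and 10 lower adjusted over the list alone. Fezf2 was at -1.56 and Dmrta2 at -1.18, while Lef1 rose (0.95). Progenitor and newborn neuron genes rose (median 1.20, adjusted p = 0.00284), with adjusted p = 0.171 with an estimated correlation. Of 7 members, 4 were higher, 1 lower and 2 not passing, or 4 higher and 1 lower adjusted over the list alone. Doublecortin (Dcx, 1.20) and Sox11 (1.40) were higher along with Top2a. Neurod1 was lower (-0.99), a call lost after the subtraction (adjusted p = 0.222).

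The extracellular matrix list tested lower (median -0.36, adjusted p = 0.00229) and held at adjusted p = 0.0342 with an estimated correlation. Of 18 members, 1 was higher, 4 lower and 13 not passing, or 1 higher and 6 lower adjusted over the list alone. The laminin gene Lama2 was at -0.63, lost without animal 977 (adjusted p = 0.0867), and Hapln4 at -0.91, lost after the subtraction (adjusted p = 0.762). The list of synapse formation and engulfment tested lower (median -0.24, adjusted p = 0.0189), with adjusted p = 0.318 with an estimated correlation. Of 16 members, 1 was higher, 3 lower and 12 not passing, or 1 higher and 4 lower adjusted over the list alone. Tgfb2 was at -0.82, while chordin-like 1 (Chrdl1) rose (1.44), and the list call was lost after the subtraction (adjusted p = 0.0817). The list of Hedgehog signalling tested lower (median -0.29, adjusted p = 0.0151), with adjusted p = 0.194 with an estimated correlation. Of 10 members, 1 was higher, 2 lower and 7 not passing, or 1 higher and 5 lower adjusted over the list alone. The co-receptor gene Boc was at -0.92, lost at a pseudocount of 0.1 (adjusted p = 0.0679). With animals 974 and 977 left out the Hedgehog signalling call was lost (adjusted p = 0.0639). The A2-type reactive astrocyte genes, of which 3 were measured, fell (median -0.91, adjusted p = 0.0378), with adjusted p = 0.186 with an estimated correlation. Ptgs2 was at -0.91 and S100a10 at -1.98, and the list was lost without animal 977 (adjusted p = 0.0694). Of 3 members, 0 were higher, 2 lower and 1 not passing, or 0 higher and 2 lower adjusted over the list alone. Genes of glycolysis and glycogen had a median -0.12, adjusted p = 0.0255, and a median of 0.00252 with no scaling. They had adjusted p = 0.656 with an estimated correlation, and the call was lost without animal 974 (adjusted p = 0.0755) or 977 (adjusted p = 0.0667). Of 24 members, 0 were higher, 1 lower and 23 not passing, or 0 higher and 0 lower adjusted over the list alone. Genes of cytosolic ribosomal proteins had a median -0.08, adjusted p = 0.0207, and a median of 0.05 with no scaling, and 0 of 74 members passed. They had adjusted p = 0.656 with an estimated correlation, and the call was lost without animal 970 (adjusted p = 0.0594).

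Among lists that did not pass, single genes still differed. The G protein-coupled receptor list (-0.08, adjusted p = 0.325) held the cannabinoid receptor gene Cnr1 (1.60) and the GABA-B receptor gene Gabbr2 (1.40) as higher, and Lpar4 as lower (-1.05). The calcium list (-0.07, adjusted p = 0.662), whose mean of 0.12 and upward test opposed its median, held the release channel genes Itpr1 (1.73) and Ryr3 (2.04) as higher. The Wnt list (0.08, adjusted p = 0.325) held Sfrp1 (1.83) as higher and the receptor gene Fzd9 (-1.45) as lower. The Notch list (-0.07, adjusted p = 0.544) held Notch3 (1.02) and Jag1 (-0.77), and the lipid list (-0.10, adjusted p = 0.144) the fatty acid-binding protein gene Fabp7 (-1.75). The thyroid hormone list (-0.02, adjusted p = 0.0734), with a mean of 0.77 and an upward test against its median, held Crym, the retinoid receptor gene Rxrg (2.07) and Hr (1.26). The remaining lists did not pass either: connexins (-0.23, adjusted p = 0.112), oxidative phosphorylation (-0.07, adjusted p = 0.132), A1-type (-0.06, adjusted p = 0.639), immediate early (0.10, adjusted p = 0.840) and interferon genes (-0.11, adjusted p = 0.366). The same held for oligodendrocyte precursor (0.07, adjusted p = 0.71), microglial (0.27, adjusted p = 0.132), endothelial (0.08, adjusted p = 0.860), mural (0.07, adjusted p = 0.544) and ependymal genes (0.45, adjusted p = 0.698), of which the ependymal mean, -0.13, opposed its median and test.

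**Figure D3:**
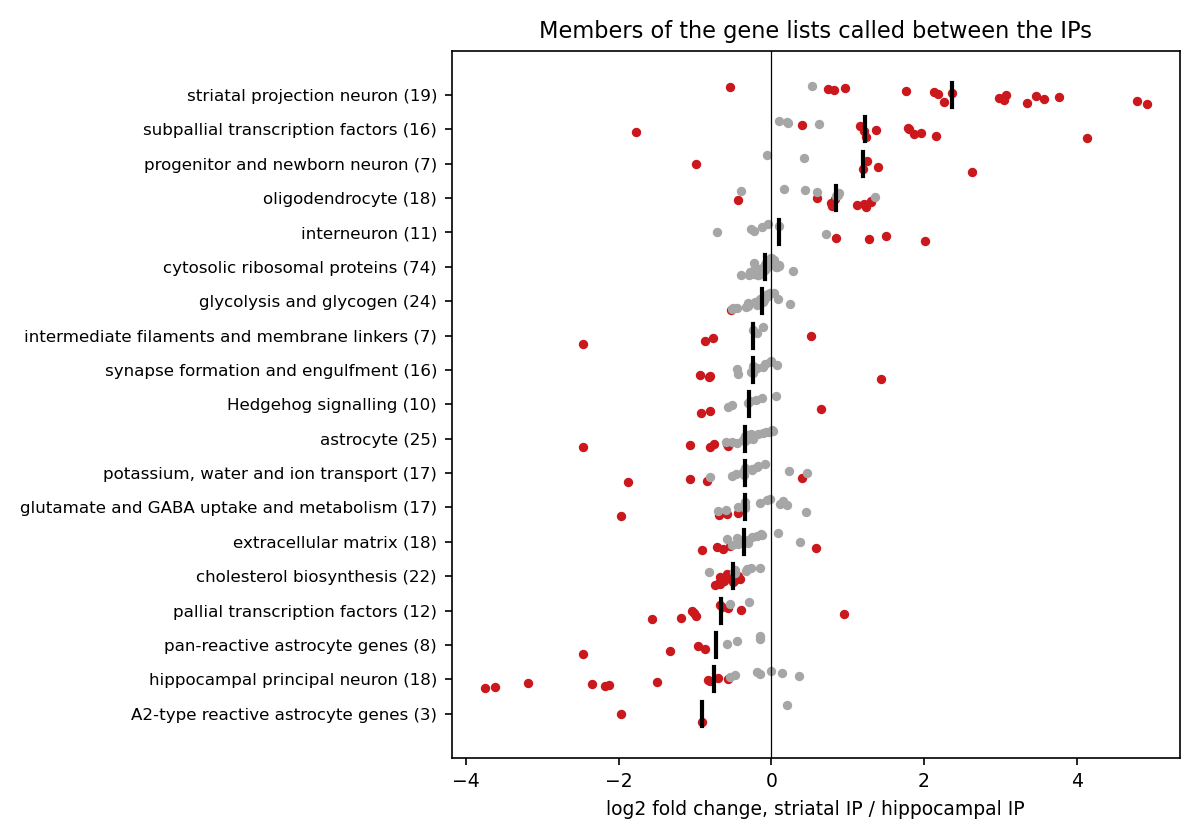
Log2 fold change between striatal and hippocampal IP of each member of the 19 lists that passed, with the number of members after each name. Red points passed adjusted p 0.05 over all genes, grey points did not, and black bars mark list medians.

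In limma across all 16 libraries, the 1640 genes called were 12.2% of those tested. Tested against a 1.5-fold change, 190 genes were higher and 95 lower, and Aqp4, Gjb6, Vim, Aspg, Cyp51, Sqle, Kcnk2, Lef1, Tgfb2, Jag1 and Hr were not among them. With no scaling 443 genes were lower, and 169 of the IP-enriched genes. With the animals as blocks in a fit of the 8 IP libraries alone, 1773 genes were higher and 1628 lower, and the IP-enriched genes numbered 161 and 764. Without the striatal IP of animal 974, 627 genes were higher, and the IP-enriched genes lower in striatum numbered 195 without the hippocampal IP of animal 970 and 195 without that of 971. Leaving out whole animals gave 607 higher and 365 lower without animal 970, 562 and 361 without 971, and 478 and 340 without 977. Leaving out animals 974 and 977, whose carry-over was larger, gave 471 and 314, leaving out striatal inputs 971 and 974 gave 1058 lower, and subtracting the carry-over gave 599 higher. Xist and Y-linked genes also parted animals 974 and 977 from 970 and 971, so leaving them out cannot part carry-over from sex.

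The inputs gave the regional difference of the whole tissue. Striatal projection neuron genes rose in striatal input (median 4.53, adjusted p = 2.58e-25) and held at adjusted p = 0.00948 with an estimated correlation. Of 19 members, 19 were higher, 0 lower and 0 not passing, or 19 higher and 0 lower adjusted over the list alone. Penk stood at 763 ± 88.9 against 9.45 ± 0.611 (log2 fold change 6.19 ± 0.22, adjusted p = 8.31e-12), with Drd2 at 6.64. Hippocampal principal neuron genes fell (median -2.47, adjusted p = 2.21e-16) and held at adjusted p = 0.00544 with an estimated correlation. Of 18 members, 0 were higher, 16 lower and 2 not passing, or 0 higher and 16 lower adjusted over the list alone. Nrn1 stood at 1.43 ± 0.849 against 125 ± 2.86 (log2 fold change -5.77 ± 0.21, adjusted p = 1.16e-11), with Neurod6 at -5.06 and Neurod2 at -4.61. Gfap was lower in striatal input (log2 fold change -2.33 ± 0.22, adjusted p = 5.82e-07), and Aldh1l1 (-0.04, adjusted p = 0.900) and Rpl22 (-0.26, adjusted p = 0.0648) did not pass. Crym was lower in striatal input, at 43.2 ± 5.77 against 75.8 ± 8.58 (log2 fold change -0.80 ± 0.23, adjusted p = 0.0140). This was the opposite direction to IP, and the call was lost without animal 970 (adjusted p = 0.0589).

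Other large rises in striatal input were the sodium channel subunit gene Scn4b (5.75), Cd4 (5.68) and the tachykinin gene Tac1 (5.16), and other large falls were the vesicular glutamate transporter gene Slc17a7 (-5.54), Fam19a1 (-4.57) and Cck (-4.49). Oligodendrocyte genes rose (median 1.01, adjusted p = 1.22e-06), with adjusted p = 0.434 with an estimated correlation. Of 18 members, 13 were higher, 0 lower and 5 not passing, or 13 higher and 0 lower adjusted over the list alone. Subpallial factors rose (median 1.56, adjusted p = 2.01e-13), with Six3 at 4.55, and held at adjusted p = 0.00135 with an estimated correlation. Of 16 members, 14 were higher, 0 lower and 2 not passing, or 14 higher and 0 lower adjusted over the list alone. Pallial factors fell (median -1.29, adjusted p = 1.39e-05), with Fezf2 at -3.36, and held at adjusted p = 0.0485 with an estimated correlation. Of 12 members, 0 were higher, 9 lower and 3 not passing, or 0 higher and 9 lower adjusted over the list alone. Pan-neuronal genes fell (median -0.61, adjusted p = 0.00319), with Stmn2 at -1.66, and had adjusted p = 0.610 with an estimated correlation. Of 16 members, 0 were higher, 9 lower and 7 not passing, or 0 higher and 10 lower adjusted over the list alone. The list of cytosolic ribosomal proteins tested lower (median -0.40, adjusted p = 0.00280), with adjusted p = 0.742 with an estimated correlation. Of 74 members, 1 was higher, 26 lower and 47 not passing, or 1 higher and 26 lower adjusted over the list alone. That of oxidative phosphorylation, nuclear-encoded, tested lower (median -0.34, adjusted p = 0.0131), with adjusted p = 0.861 with an estimated correlation. Of 89 members, 3 were higher, 32 lower and 54 not passing, or 3 higher and 35 lower adjusted over the list alone. Both of the last calls were lost without striatal inputs 971 and 974 (adjusted p = 0.458 and 0.317). Astrocyte genes (-0.22, adjusted p = 0.487) and cholesterol genes (-0.23, adjusted p = 0.249) did not pass. Nor did microglial (0.22) and glycolysis genes (-0.59, each adjusted p = 0.0672). The microglial and glycolysis lists did with animal blocks (0.0420, 0.0394) or a rotation test. In 6 lists that did not pass, the mean opposed the median. They were oligodendrocyte precursors (median -0.08, mean 0.35), progenitors (0.11, -0.42), ion transport (-0.21, 0.03), lipid (0.13, -0.06), Hedgehog (-0.25, 0.03) and Wnt genes (0.05, -0.04). Striatal inputs 971 and 974 stood apart, with Rn45s, a ribosomal RNA precursor, at 1003 and 418 FPKM against 3030 to 5649 in the other inputs, and the nuclear RNA Malat1 at 7499 and 9021 against 2489 to 4367.

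In limma, 2077 genes were higher and 2843 lower in striatal input, 36.5% of those tested. Without animal 971 these were 1060 and 1526, and without striatal inputs 971 and 974, 1337 were higher. Leaving out animals 974 and 977 gave 1690 lower. Of the genes higher in striatal IP, 616 were also higher in striatal input (150.3 for independent lists), and of those lower, 387 were also lower (140.4). Opposite directions were found for 39 and 30 genes, where independent lists would share 205.8 and 102.5. Across genes, which are not independent replicates, the regional fold changes in IP and input had r = 0.556 and rho = 0.425.

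**Figure D4:**
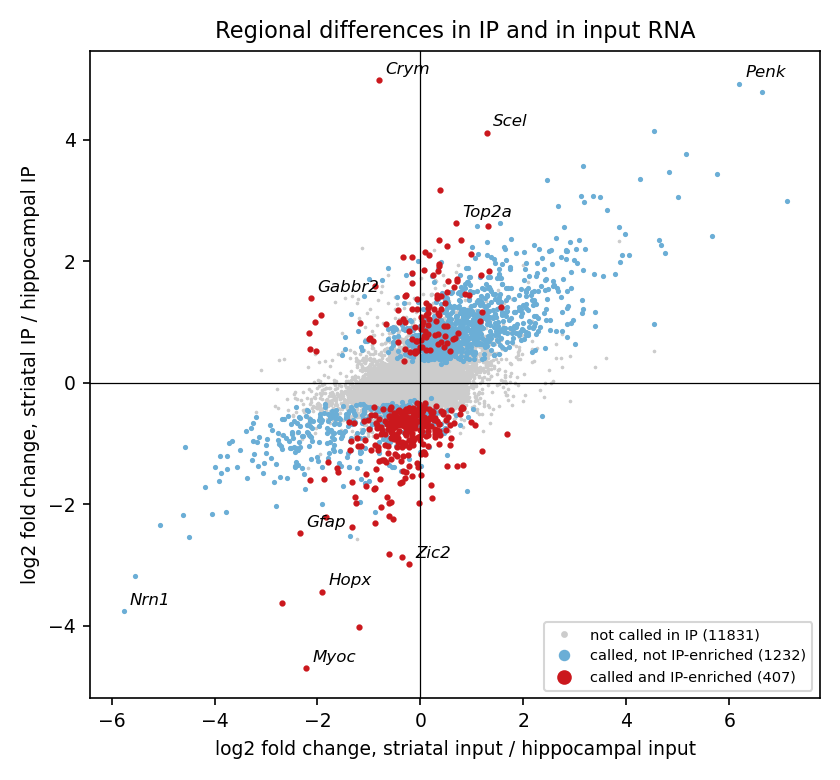
Log2 fold change between striatum and hippocampus in IP (vertical) against input (horizontal), 1 point per gene. Red points are the 407 called IP-enriched genes and blue points the other called genes, with Crym at 4.98 in IP and -0.80 in input.

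The last comparison asked which genes differed between regions in IP beyond the difference in input, where higher means more towards striatum in IP than in input. Crym had the largest difference in either direction, log2 fold change 5.78 ± 0.33, adjusted p = 5.09e-08, and among higher genes Gabbr2, at 46.3 ± 14.2 in striatal IP and 16.4 ± 2.03 in hippocampal IP, was next (log2 fold change 3.51 ± 0.24, adjusted p = 3.01e-07). Fam19a1 (3.51) and the protocadherin gene Pcdh20 (3.32) were also higher. Fam19a1 stood at no more than 0.99 scaled FPKM in striatal input, so a fall in hippocampal IP alone gives its positive value. The negative end held Ppp1r1b, the gene of the dopamine-regulated phosphatase inhibitor DARPP-32 (-4.02), Ido1 (-3.57), Cd4 (-3.26), the guanylate cyclase gene Gucy1a3 (-3.20) and the choline transporter gene Slc5a7 (-3.19). Cd4 and Slc5a7 lost their calls in a weighted fit of estimated reads (adjusted p = 0.243 and 0.17), and with Ido1 they lay near 0 in hippocampal IP. Gfap (-0.14, adjusted p = 0.813), Aldh1l1 (-0.03, adjusted p = 0.954) and Rpl22 (0.18, adjusted p = 0.443) did not pass.

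The microRNA locus Mir6911 (3.35, adjusted p = 0.0431) lost its call with the animals as blocks (adjusted p = 0.0641), and Mir218-1 (3.13, adjusted p = 0.0095) at a pseudocount of 0.1 (adjusted p = 0.125). Hippocampal principal neuron genes were higher (median 1.97, adjusted p = 5.21e-12), with C1ql2 at 2.63, and held at adjusted p = 0.0386 with an estimated correlation. Some members were low in striatal input, such as Neurod2 (0.352 to 0.968 scaled FPKM) and Neurod6 (0.455 to 2.35). There the scale can show little fall, so a fall in hippocampal IP alone gives a positive value. Of 18 members, 15 were higher, 1 lower and 2 not passing, or 15 higher and 1 lower adjusted over the list alone. Striatal projection neuron genes were lower (median -1.80, adjusted p = 9.15e-13, or 0.0991 with an estimated correlation). Ido1 and Drd2 were low in hippocampal input, which likewise gives negative values. Of 19 members, 0 were higher, 13 lower and 6 not passing, or 0 higher and 14 lower adjusted over the list alone. The opioid peptide gene Pdyn was at -2.90. Genes of the subpallial transcription factors were lower (median -0.53, adjusted p = 4.91e-05) and held at adjusted p = 0.0454 with an estimated correlation. Of 16 members, 2 were higher, 8 lower and 6 not passing, or 2 higher and 9 lower adjusted over the list alone. Zic1 was at -2.68, while Dlx2 was higher (2.06). Progenitor genes were higher (median 0.88, adjusted p = 0.000142), with Neurod1 at 2.72, and had adjusted p = 0.117 with an estimated correlation. Neurod1 was near 0 in striatum, so its value came from the fall in hippocampal IP. Of 7 members, 5 were higher, 0 lower and 2 not passing, or 7 higher and 0 lower adjusted over the list alone. The pallial list tested higher (median 0.72, adjusted p = 0.0117), with adjusted p = 0.366 with an estimated correlation. Of 12 members, 6 were higher, 2 lower and 4 not passing, or 8 higher and 2 lower adjusted over the list alone. The pan-neuronal list tested higher (median 0.56, adjusted p = 0.0152), with adjusted p = 0.704 with an estimated correlation. Of 16 members, 4 were higher, 0 lower and 12 not passing, or 5 higher and 0 lower adjusted over the list alone. The list of cholesterol biosynthesis tested lower (median -0.28, adjusted p = 0.00170), with adjusted p = 0.398 with an estimated correlation. Of 22 members, 0 were higher, 4 lower and 18 not passing, or 0 higher and 7 lower adjusted over the list alone. The list of potassium, water and ion transport tested lower (median -0.25, adjusted p = 0.00753), with adjusted p = 0.457 with an estimated correlation, and Kcnk2 was at -2.53. Of 17 members, 0 were higher, 4 lower and 13 not passing, or 0 higher and 4 lower adjusted over the list alone. The astrocyte list tested lower (median -0.14, adjusted p = 0.0360), with adjusted p = 0.760 with an estimated correlation. Of 25 members, 0 were higher, 1 lower and 24 not passing, or 0 higher and 1 lower adjusted over the list alone. The bicarbonate transporter gene Slc4a4 was at -1.66. The oligodendrocyte list tested lower (median -0.35, adjusted p = 0.0387), with adjusted p = 0.706 with an estimated correlation. Of 18 members, 0 were higher, 2 lower and 16 not passing, or 0 higher and 2 lower adjusted over the list alone. The astrocyte call was lost without animal 977 (adjusted p = 0.113), the oligodendrocyte call without animal 970 (adjusted p = 0.208), and the subpallial and cholesterol calls with animals 974 and 977 left out (adjusted p = 0.155 and 0.0593). The pan-neuronal call was lost with no scaling (adjusted p = 0.0638), and C1ql2 and Neurod1 lost theirs in the weighted fit of estimated reads (adjusted p = 0.136 and 0.138).

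In limma, 1181 genes were higher and 723 lower, so 62% of the calls were rises, against 48.8% with median-of-ratios factors and 72.2% with no scaling. The counts were 783 higher without the hippocampal input of animal 971, and 1814 higher and 1212 lower without the striatal input of animal 977. Without a whole animal they were 444 and 312 without 970, 366 and 224 without 971, and 671 and 479 without 977, and with both 974 and 977 left out they were 496 and 428. Of the IP-enriched genes, 66 higher and 111 lower in striatal IP also passed this test in the same direction.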

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

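The tests of the striatal and hippocampal neuron, cholesterol and progenitor genes were chosen after those results were seen, and for the scaling, whole-tissue, cholesterol dilution and progenitor carry-over tests the tested values had been seen as well.

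Splits of the libraries into other groups of the same size put a limited bound on chance. In each of the 6 gene counts, only 1 of 35 splits, the real one, was as large: 8846 genes in hippocampal IP against input (highest other 1), 8783 in striatum (336), 1640 between IPs (176), 4920 between inputs (1), 1904 for the difference of differences (1) and 407 for the IP-enriched genes (5). For the IP-enriched genes the IP and input of an animal's region were moved together, and with the IP libraries moved alone the highest other was 22. Among the 8 splits that part all animals' pairs, the highest other counts were 0, 336, 0, 1, 1 and 0. The counts of lists did not stand out in this way. As many lists were called in 4 of 35 splits for hippocampal IP against input (26, highest other 26), 4 for striatum (28 and 29), 5 between IPs (19 and 22), 13 between inputs (8 and 11) and 4 for the difference of differences (10 and 11). In the first 4 comparisons every rival split exchanged a single library of each group, which keeps much of the real difference. Such splits do not measure chance for the number of lists called. In splits that mixed both groups evenly, at most 3, 3, 16, 4 and 10 lists were called in the 5 comparisons. With all pairs parted the highest other list counts were 26, 29, 18, 8 and 7.

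Striatal projection neuron genes were higher in striatal IP, and carry-over of unbound tissue RNA is a candidate explanation. After subtraction their median fell from 2.37 to 0.81 with quartiles of -0.03 and 1.90, so the 2 readings cannot be told apart, and 6 of the 17 members called higher stayed so, among them Adcy5 (3.34), Pde10a (2.58) and Rgs9 (2.55). Their striatal IP level was 20.8% of input (quartiles 9.69 and 26.3) against 12.4% (6.43 and 17) for pan-neuronal genes, with ratios averaged over animals, which overlaps. Hippocampal principal neuron genes went from -0.75 to -0.14 (quartiles -0.94 and 0.04) with 7 of 11 calls left, which carry-over could explain, although Nrn1 (-3.15) and Dsp (-3.58) stayed far below 0. A difference between the astrocytes of the 2 regions stays open as untested.

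Cholesterol synthesis genes were lower in striatal IP, and a carry-over that was larger there as a share of input might have diluted them. Dilution would lower all IP-enriched genes alike. The 1539 other genes enriched above log2 1 in both regions had a median of -0.17 (quartiles -0.35 and -0.01), against -0.50 (-0.63 and -0.44) for the cholesterol genes, which argues against dilution as the whole cause and leaves a part of it possible. Scaling did not account for it either, with medians of -0.37 and -0.56 under the other 2 scalings. In the inputs the median was -0.23 (quartiles -0.51 and -0.01), so a difference of the whole tissue cannot be told apart from a difference of astrocytes. The cause of the regional difference stays open as untested.

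The progenitor list was higher in striatal IP, and carry-over from newborn cells could be the source. The level of its 7 members in striatal IP had a median of 138% of input (quartiles 117 and 442) against 11.0% (6.49 and 15.8) for pan-neuronal genes, with ratios of group means because a member was near 0 in input, which argues against unbound RNA alone. For Mki67, Top2a, Dcx and Sox11, picked because they were higher, the lowest median difference with an animal left out was 1.20 and the highest 1.44 (1.33 with all), so it did not rest on 1 animal. Whether dividing cells carried the tag stays open as untested.

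By the rule for libraries apart from their group, 8 of 167 groups (4.8%) were marked, where about 1 in 20, or 8.3, would be by chance. The gap as a share of the range was 0.852 for Rpl22 in striatal input of animal 971 (2.418 against 3.365 to 3.53), 0.846 for 2610034M16Rik in hippocampal IP of 977 (3.21 against 2.484 to 2.596) and 0.979 for Mir667 in the same library (4.467 against 1.221 to 1.29). It was 0.918 for Sfrp5 in striatal IP of 974 (2.357 against 7.413 to 7.865), 0.891 for Fam19a1 in striatal input of 974 (0.2336 against 0.9069 to 0.9896) and 0.837 for Mir6911 in the same library (0 against 14.05 to 16.79). It was 1 for Ido1 in hippocampal IP of 970 (0.01857 against 0) and 0.870 for Ppp1r1b in hippocampal input of 974 (8.511 against 12.05 to 12.57).

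Enrichment of IP over input (striatum minus hippocampus, log2) differed for 29 genes listed here, among others. It was lower in striatum for Cd4 (-3.26), Serpinf1 (-2.82), Zic2 (-2.76), Cald1 (-2.51), Myoc (-2.48), Scn4b (-2.32), Rtp1 (-2.21), Drd2 (-1.85), Apod (-1.59), Hopx (-1.53), Cybrd1 (-1.43), Penk (-1.27), Prelp (-1.05) and Dsp (-0.93). It was higher for 2610034M16Rik (1.13), Basp1 (1.19), Ube2c (1.57), Top2a (1.93), Hist1h2bm (1.94), Cck (1.95), Sfrp5 (1.98), Nrn1 (2.01), Slc17a7 (2.36), Neurod2 (2.44), Neurod6 (2.71), Prss56 (2.79), Scel (2.82), Fam19a1 (3.51) and Crym (5.77). Among lists it was lower for astrocyte (-0.14), striatal projection neuron (-1.79), oligodendrocyte (-0.35), ion transport (-0.25), cholesterol (-0.28) and subpallial genes (-0.53), and higher for pan-neuronal (0.56), hippocampal principal neuron (1.97), progenitor (0.88) and pallial genes (0.72). With an estimated correlation the hippocampal principal neuron and subpallial calls held (adjusted p = 0.0386 and 0.0454). The others were lost (0.0991 to 0.760). Of the 25 astrocyte members, 1 was called. Neurod2, Neurod6 and Fam19a1 were low in striatal input, where little fall can show. For Cd4, Drd2, Penk and Scn4b, very low in hippocampal IP, and Dsp, very low in striatum, the sign is uncertain on this scale.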

How the results depend on the processing

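The leaving out of striatal inputs 971 and 974, of animals 974 and 977, the carry-over subtraction, the filter at 5 FPKM and the fit of estimated reads were chosen after the files were seen, and the other alternatives before the data were examined.

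The planned count tests were not run because the unit is FPKM. A weighted fit of reads estimated from FPKM, depth and length ran on 13311 genes, 159 fewer, and gave 180 IP-enriched genes higher in striatal IP. In it the difference of differences changed sign for Drd1a (0.52), Kl (-0.65) and Lhfpl3 (0.000162). Depth was lowest in striatal input (4.14 to 8.96, in units of 1e6 fragments), which limits calls of low genes there.

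With no scaling, the median of all fold changes shifted by -0.41, -0.24, 0.11, -0.07 and 0.17 in the 5 comparisons. Genes higher in hippocampal IP numbered 2496 and lower 7113, genes lower in striatal than hippocampal IP 443, and IP-enriched genes lower there 169. A filter at 5 FPKM gave 53 IP-enriched genes higher in striatal IP.

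At adjusted p under 0.01, 540 genes were higher and 366 lower between IPs, 1241 and 1763 between inputs, 598 and 366 for the difference of differences, and 168 IP-enriched genes were lower. Tested against 1.5-fold, 2018 and 2382 passed in hippocampus, 2098 and 1967 in striatum, 190 and 95 between IPs, 456 and 598 between inputs, 215 and 121 for the difference of differences, and 37 and 49 of the IP-enriched genes.

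With the animal as a block in all 16 libraries, the counts were 3925 and 5122 in hippocampus, 4426 and 4556 in striatum, 1155 and 781 between IPs, 2253 and 3075 between inputs, and 1334 and 817 for the difference of differences. In the 8 libraries compared with the block, 1773 and 1628 genes passed between IPs, and 161 and 764 IP-enriched genes, and without it 1828 genes were lower between inputs. The block also changed list calls: striatal projection neuron genes in hippocampal IP over input were lost (0.0663), while calcium genes in striatum (0.0489), immediate early genes in hippocampus (0.0371) and striatum (0.0489), and microglial (0.0420) and glycolysis genes (0.0394) between inputs passed, and it changed no other list call.

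The criteria of the IP-enriched set moved it too. Any enrichment past adjusted p 0.05 gave 174 genes higher in striatal IP, enrichment in both regions 37, and a pass of the difference of differences in the same direction 66 higher and 111 lower.

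Leaving out each library or animal in turn gave 3325 to 4102 higher and 4152 to 5285 lower in hippocampus, 3539 to 4383 and 3582 to 4448 in striatum, 478 to 1201 and 340 to 856 between IPs, 1060 to 2620 and 1526 to 3339 between inputs, 366 to 1814 and 224 to 1212 for the difference of differences, and 60 to 129 and 152 to 373 IP-enriched genes. Lists called with an animal left out were 25 to 27, 26 to 29, 17 to 20, 9 to 10 and 9 to 11.

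Among single libraries, leaving out the hippocampal IP of animal 970 gave 195 IP-enriched genes lower in striatal IP, as did that of 971. Without the hippocampal input of 971, 783 genes were higher for the difference of differences, without the striatal input of 977, 1814 and 1212, and without the striatal IP of 974, 627 genes were higher between IPs. Without animal 970 the counts were 607 and 365 between IPs, 444 and 312 for the difference of differences, and 60 and 165 IP-enriched genes. Without 971 they were 562 and 361, 366 and 224, and 60 and 165, with 1060 and 1526 between inputs, and without 977 they were 478 and 340, 671 and 479, and 69 and 152.

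Without striatal inputs 971 and 974, 1058 genes were lower between IPs and 1337 higher between inputs. Without animals 974 and 977, 471 and 314 passed between IPs, 496 and 428 for the difference of differences, 57 and 141 IP-enriched genes, and 1690 were lower between inputs. With carry-over subtracted, 599 genes were higher between IPs, and Egr1 (-0.62), Lpl (-0.19), Penk (-0.15) and Ugt8a (-0.013) turned negative. For Penk this followed from the size of the subtracted share.

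With an estimated correlation 8, 4, 8, 4 and 2 lists were called in the 5 comparisons, against 26, 28, 19, 8 and 10. With a rotation test 22 lists passed between inputs, and the A1-type list in hippocampus passed downward (adjusted p = 0.0324) against a median of 0.265. For each of these changed counts the cause was not tested. In total 383 counts stayed within 1.5-fold and 75 did not.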

Other observations

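The genes and libraries of this part were chosen after the result was seen.

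A set of 69 genes differed between the regions in opposite directions in IP and input, 39 higher and 30 lower in striatal IP. Dkk3, which encodes a secreted dickkopf family protein, stood at 434.2 ± 89.9 in striatal against 215.9 ± 42.4 in hippocampal IP (log2 1.002, adjusted p = 0.00229), and at 42.2 ± 11.9 against 172 ± 5.202 in the inputs (-2.04, adjusted p = 5.15e-07). Rspo3, the gene of a secreted Wnt enhancer, had 1.11 in IP and -1.94 in input, and Tmem159 had 1.71 and -1.01. The opposite order was found for the zinc finger gene Zfp503, at -1.13 in IP and 1.20 in input, and for Zic1, at -1.78 and 0.90. Gabbr2 had 1.40 in IP and -2.12 in input, with 46.3 ± 14.2 in striatal IP and 72.8 ± 2.32 in hippocampal input. The small GTPase gene Rab33a had 1.42 and -1.10.

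Sex-linked genes parted the animals. Xist, the RNA of the inactive X chromosome, stood at 11.3 to 43.3 FPKM in all libraries of animals 970 and 971 and at no more than 0.088 in those of 974 and 977. In the hippocampal input of 970, Y-linked genes stood at 0.615 (Ddx3y), 0.891 (Eif2s3y), 0.486 (Kdm5d) and 0.188 (Uty), against 10.4, 27.3, 8.69 and 6.003 in that of 974. In the other libraries of 970 and 971 they were at 0, except Kdm5d at 0.017 in the hippocampal input of 971. Apart from sex-linked genes, 5 genes of the 32 that differed between animals deviated by more than log2 1: Tuba1c (1.38 in 974), Psmc3ip (1.29 in 970), Mamdc2 (1.17 in 974), BC002163 (1.15 in 977) and Tmem181b-ps (-1.07 in 970).

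Striatal inputs 971 and 974 held less of the ribosomal RNA precursor Rn45s, at 1003 and 418 FPKM, and more Malat1, at 7499 and 9021, than striatal inputs 970 and 977, where Rn45s stood at 4894 and 5122 and Malat1 at 4129 and 4367. The circular RNA locus Cdr1 stood at 2481 and 5518 in the former and at 1250 and 616 in the latter.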
